A study of Drosophila melanogaster with 2 samples.

How the data were processed

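Chromatin bound by Odd-eGFP was recovered with an anti-GFP antibody from whole mixed-sex Drosophila melanogaster embryos aged 0 to 16 h, in 2 biological replicates of 1 group, per the labels. The labels number the replicates as separate biological replicates, and the analysis kept them as such. The deposited files used were 8 peak lists: for each of the builds dm6 and dm3, the relaxed list of each replicate, the relaxed list of the pooled replicates, and the IDR list. Per the text records deposited with each library, the list of a replicate was made from that replicate's alignments and a control, the pooled list from the alignments of both replicates and a control, and the IDR list from the 3 relaxed lists. Which peak caller made them, its version, the aligner, the read filters and the IDR threshold are not given in the sources used here. The control library was not analysed here.

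The value used from each list was the deposited signal value, a score that the caller gave each peak. It is the authors' value, it grows with depth, and it served only to rank and filter peaks within a list. The position of the summit was taken from the deposited offset, another number of the same record, counted in bp from the start of the peak. Coordinates are 1-based on dm6. The reference was the Ensembl release 115 annotation and the NCBI Release 6 sequence of the genome, and the peaks of the dm6 lists lay within the lengths of its chromosome arms. No dm3 reference was used, so dm3 lists entered only counts of peaks and agreement of replicates.

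Since the lists hold peaks and not reads, the depth of each replicate is unknown. The relaxed lists hold 30000 peaks each, so their length says nothing about depth. The exact 95% binomial (Clopper-Pearson) intervals on shares cover counting of peaks or genes only and not the spread between embryos. With 1 group of 2 replicates no test between conditions or across samples exists, and each p describes these peaks.

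Replicates were compared over as many of the strongest peaks of each as the IDR list holds, 4291, with summits within 100 bp counted as matched, against 100 random placements on the same chromosomes. Spearman's rho was taken over IDR peaks whose summit was covered by a peak of each replicate. Each summit was assigned to 1 of 7 classes in the order promoter (within 500 bp of a TSS), 5' untranslated, 3' untranslated, coding exon, other exon, intron and intergenic. The class shares and the counts per chromosome were tested against 1000 random placements. Gene lists were tested by the number of members with an IDR summit in the gene span or within 5 kb of it, called the territory here, by a permutation test, against 10000 random lists of protein-coding genes matched on decile of span length. Of the 22 lists, 21 were found in full, and 12 of the 13 leg and disc genes were found. Words were counted on both strands within 100 bp of the summit and in windows of 201 bp centred 1000 bp to each side, with an exact two-sided sign test of the summit against the left flank. The relation of the word of Odd to peak rank was tested with 100000 permutations. P-values were adjusted by Benjamini-Hochberg within each family, with a threshold of 0.05.

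The tests, gene lists, words and alternatives were fixed before the data were examined. The genes named are the 4 of the odd family, the gene with the nearest protein-coding TSS of each of the 15 strongest IDR peaks, up to 3 members of each list with the strongest summit, and the members of the pair-rule, gap and segment polarity lists without a summit. Neighbours named beside them are the genes whose TSS is nearest to the summit. The genes for, gro and E2f1, and those named only in the closing part, were chosen after their values were seen. The words of Zelda and the other factors are, like that of Odd, short consensus words recalled as background and not weight matrices.

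The alternatives were another distance for promoters, territories, words and matched summits, the gene with the nearest TSS at any distance in place of territories, the 2145 strongest IDR peaks in place of a stricter IDR (the IDR lists give no IDR value used here), other numbers of peaks, the lowest-ranked relaxed peaks as background, dinucleotide-shuffled sequence, matching among genes with a name, the dm3 lists, and each replicate alone with its 4291 strongest peaks. After the data were seen, 4 were added: 1 summit per region, matching of gene lists on the number of other TSSs in the territory as well, the gene with the nearest TSS with the limit of 5 kb kept, and counts per chromosome with no placements on Y. A planned limit of 50000 relaxed peaks took all 30000, since the list holds no more.

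The tests were tested on simulated data first. With 4291 summits placed at random, 0 of 7 location classes were called, and when part of them was moved to TSSs the promoter share found was 40.7% for 39.5% simulated. Of 100 random gene lists with no effect, 4.00% had p under 0.05, and of 20 lists of 10 genes in which each gene was given a summit, 100.0% did. These lists held singly drawn genes and the summits were placed at random, so the 4.00% does not cover lists of neighbouring genes or clustered summits. No list of fewer than 10 genes was simulated. After the word of Odd was written into 85 random windows, the count of windows with it rose by 85 (exact sign test p = 4.96e-16, against p = 1 before). The work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.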

Results

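Odd skipped (Odd) is a zinc-finger protein of the pair-rule class, the set of genes that divides the early fly embryo into segments. Its binding to chromatin was measured by ChIP-seq in a transgenic Drosophila melanogaster line that carried Odd fused at its C terminus to enhanced green fluorescent protein (eGFP). An antibody against GFP recovered the fusion protein with the DNA it was attached to. Whole embryos of both sexes, collected between 0 and 16 h after laying, made up 1 group of 2 biological replicates, and chromatin was broken by sonication to 200 to 800 bp. No second condition and no control library was analysed here, so the design implies 2 questions: how far the 2 replicates gave the same sites, and where in the genome those sites lay. Read depth per replicate is unknown, because the deposited lists hold peaks and not reads.

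On the dm6 genome build, each replicate and the pool of both had a relaxed list of 30000 peaks, background included. The list that passed the irreproducible discovery rate (IDR, a filter on how well peaks repeat between replicates) held 4291 peaks in 4020 separate regions. Of these peaks, 40 had the same start and end as another peak of the list. Peak width ranged from 116 to 831 bp with a median of 464 bp. The signal value, which is the caller's own score per peak, ranged from 144 to 2892 with a median of 219. The 4291 IDR peaks were the same peaks as the 4291 strongest of the pooled relaxed list, 14.3% of that list.

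The strongest sites of the 2 replicates lay largely at the same positions. Of the 4291 strongest peaks of replicate 1, 2863 had a summit within 100 bp of a summit among the 4291 strongest of replicate 2, a share of 66.7% (exact 95% interval 65.3 to 68.1). Summits placed at random on the same chromosomes matched in 0.659% of cases on average over 100 placements, and in 1.05% at most. Of the IDR peaks, 3100 (72.2%) had a covering peak among the strongest 4291 of both replicates, 1105 of 1 replicate and 86 of neither. The signal values of the 4198 IDR peaks covered in both replicates had a Spearman rho of 0.713 (95% interval 0.698 to 0.728), calculated across peaks, which are not independent replicates. The IDR peaks were the strongest peaks of the pool of both replicates, so this rho and the 72.2% are not independent of that selection. Over the 30000 peaks of the pooled relaxed list, rho was 0.701 for the 18233 covered in both replicates. The share of 66.7% rests on the strongest peaks of each replicate on its own. The strongest IDR peak, in an intron of CG11050, was also the strongest of each replicate. The strongest peak in the territory of brk, a repressor of Dpp target genes, ranked 219 in the IDR list and 323 in replicate 2, and no peak of replicate 1 covered its summit. The territory of brk still held a summit among the 4291 strongest peaks of replicate 1.

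**Figure D1:**
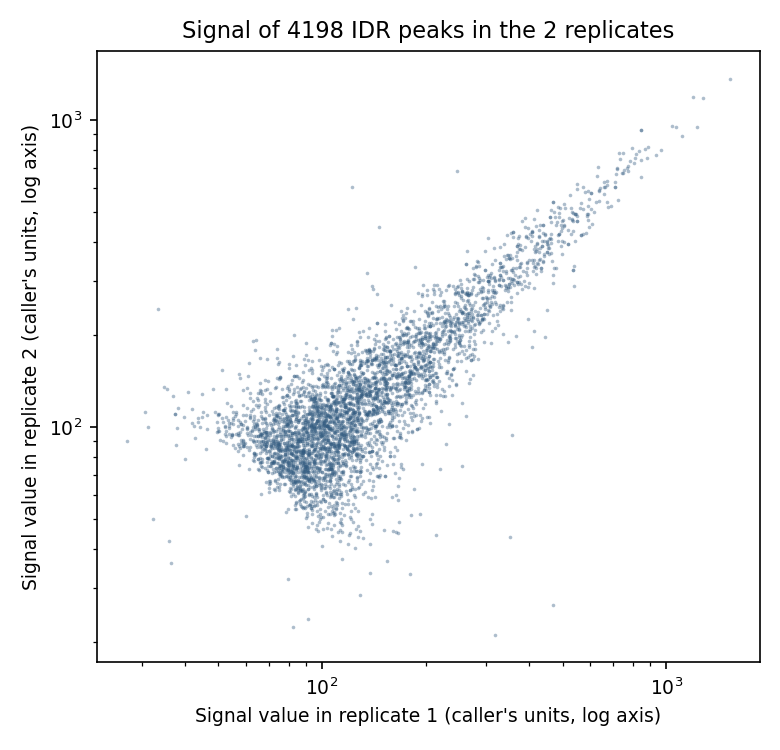
Signal value of each IDR peak in replicate 1 (x axis) and replicate 2 (y axis), both in the caller's units on log axes; each point is 1 of the 4198 IDR peaks covered in both replicates. The points rise together with a Spearman rho of 0.713 and spread most among the weaker peaks.

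Summits of Odd-eGFP were concentrated at promoters and were rare in coding sequence. Of the 4291 IDR summits, 1960 (45.7%, exact 95% interval 44.2 to 47.2) lay within 500 bp of an annotated transcription start site (TSS), against 13.6% of randomly placed summits, 3.35 times as many. Coding exons held 0.443% of summits against 13.1% of random placements, 3' untranslated regions 0.792% against 5.02%, and intergenic sequence 12.4% against 27.4%. Introns held 39.1% of summits against 39.3% at random. The median distance from a summit to the nearest protein-coding TSS was 831 bp. The promoter share was 57.6% among the 859 strongest peaks and 40.3% among the 858 weakest.

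The promoter, coding exon, 3' untranslated and intergenic shares each had an adjusted p of 0.0035 after Benjamini-Hochberg adjustment over 7 classes, from an unadjusted two-sided empirical p of 0.002, the smallest that 1000 placements give. Intron, 5' untranslated and other exon shares did not pass (adjusted p = 0.763, 0.396 and 0.283; n = 4291 summits). The 4291 lowest-ranked peaks of the pooled relaxed list, which serve as a background from the same libraries, held 17.2% at promoters, 49.3% in introns and 26.9% in intergenic sequence. The intron share, again with n = 4291 summits, was below its expectation when the promoter was widened to 1000 bp (31.7% against 36.0%, adjusted p = 0.0028) and in replicate 2 alone (36.0% against 39.3%, adjusted p = 0.0028).

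**Figure D2:**
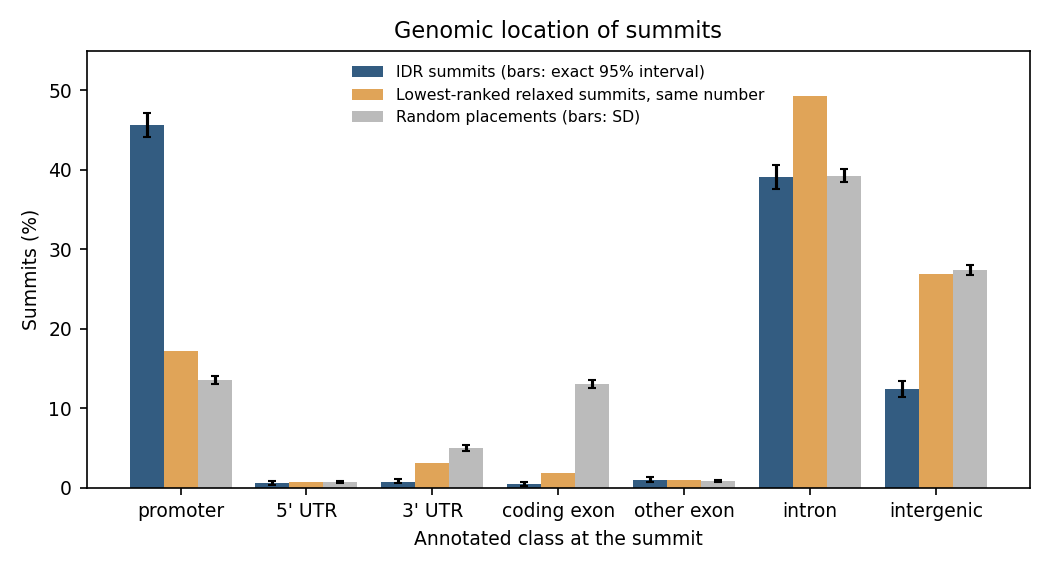
Share of summits (y axis, percent) in each annotated class (x axis) for the 4291 IDR summits, for as many of the lowest-ranked pooled relaxed summits, and for random placements on the same chromosomes; error bars are exact 95% intervals for the IDR summits and SD over placements for the random ones. Promoters held 45.7% of IDR summits, 17.2% of lowest-ranked summits and 13.6% of random placements.

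Along the chromosomes, arm 2L held more summits than its length gives and chromosome 4 fewer, with or without the Y chromosome among the 7 over which summits were spread. Arm 2L had 853 summits against 733 expected (ratio 1.16). The pooled relaxed list, background included, held 5748 peaks on 2L, 6846 on the longer arm 3L and 4999 on X. The embryos were of both sexes and males carry 1 X, so X is not a like arm for 2L. Neither the placements nor these counts allow for the copies of X. The IDR count on 2L was not tested against the pooled relaxed list. Chromosome 4 had 19 against 41.7 (ratio 0.455). Both had an adjusted p of 0.00466 over 7 chromosomes. The X chromosome, with 694 summits against 733 expected, did not pass (adjusted p = 0.157, n = 4291 summits in all), although replicate 2 alone gave 669 (adjusted p = 0.014). Likewise arm 3L, with 924 summits against 878, did not pass (adjusted p = 0.108, n = 4291), although replicate 1 alone gave 956 (adjusted p = 0.00699). No list held a peak on the Y chromosome, where 115 were expected by length, which lowers what is expected of the others. With no placements on Y, a setting chosen after seeing the data, the expected counts were 753 for 2L and 43.4 for chromosome 4 (both adjusted p = 0.00599, n = 4291). The X chromosome then passed, with 755 expected (ratio 0.919, adjusted p = 0.032, n = 4291), so its call depends on this choice, and 3L did not, with 901 expected (adjusted p = 0.453, n = 4291). The single replicates were not run without Y. Placements treated summits as independent, although the 4291 IDR peaks lie in 4020 regions, so the p-values per chromosome may be too small. Counts per chromosome with 1 summit per region were not run. Whether reads on that chromosome were kept is not given in the sources used here.

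For the strongest 15 peaks in order of signal, the nearest protein-coding TSS belonged to CG11050, Ugalt, cbt, CG14100, CG4004, px, Trl, hll, jp, sbb, PNPase, Psc, CG13323, Tina-1 and CG18549. The peak at CG11050 (2L, 6612382 to 6612972) lay in an intron with a signal of 2892. The peak at Ugalt, which encodes a transporter of UDP-galactose, lay at its promoter (X, 2703668 to 2704082, signal 2469). The peak nearest to cbt, which encodes a zinc-finger transcription factor, lay in an intron of the gene ush (2L, 480879 to 481314, signal 2400.3). Others of the 15 were nearest to genes of chromatin regulators: Trl, which encodes GAGA factor (rank 7), and Psc, a Polycomb group gene (rank 12). The peak listed under CG13323 (rank 13) was intergenic, 11910 bp from that TSS. None of the 15 summits had the word ACAGTAGC, the binding sequence of Odd used here, within 100 bp.

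Each of the 4 genes of the odd family, which share the zinc-finger domain, had an IDR summit in its span or within 5 kb, against 1.88 expected from lists of genes of the same length (adjusted permutation p = 0.279). With 4 genes, this largest possible count gave an unadjusted permutation p of 0.0934, so no excess could have passed in this setting. The list passed when each summit was given only to the gene with the nearest TSS, at any distance (25.1% expected, adjusted permutation p = 0.0297). Since drm, sob and odd lie together in 1 dense stretch and random lists draw genes singly, this p does not allow for their closeness. The strongest summit at odd (2L, peak 3606873 to 3607328) lay 315 bp from its TSS with a signal of 930.4, rank 110 in the IDR list, 125 in replicate 1 and 101 in replicate 2. The strongest summits at bowl and drm also lay at their promoters, 274 and 237 bp from the TSS, at ranks 331 and 401. That at sob ranked 967 and lay in intergenic sequence, nearest to the TSS of CG43815. A slightly weaker summit lay at the promoter of sob, 171 bp from its TSS, at rank 1060. Between 3534247 and 3646756 on 2L, a stretch that holds drm, sob, odd and part of for, the IDR list had 24 summits. The strongest of them, rank 22, lay 367 bp from a TSS of for, which encodes a cGMP-dependent protein kinase.

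**Figure D3:**
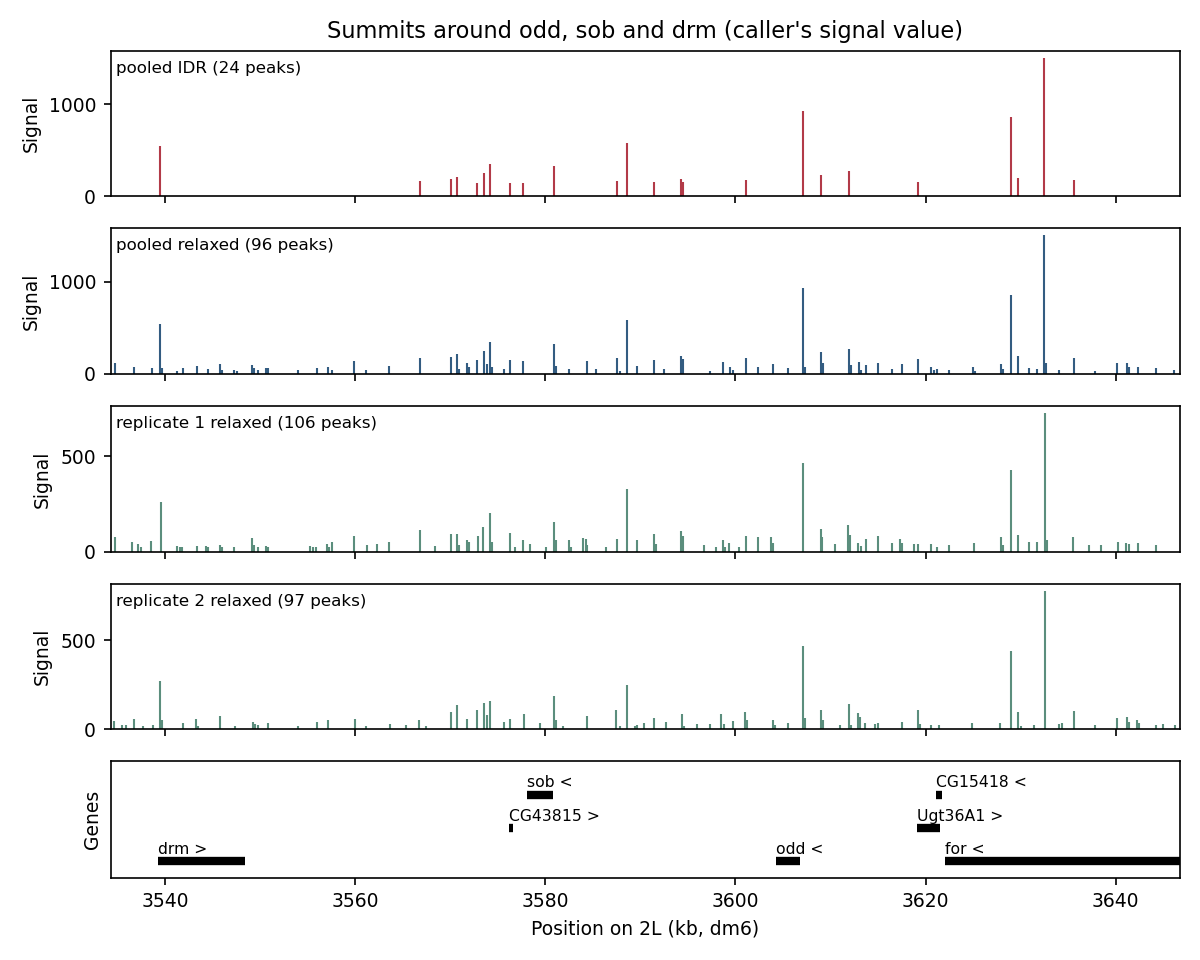
Summits between 3534247 and 3646756 on 2L (dm6; x axis in kb) in the pooled IDR list, the pooled relaxed list and the relaxed list of each replicate; the height of each line is the caller's signal value (y axis, scaled per list), and the lowest panel shows protein-coding genes with their strand. The summit at the odd promoter had a signal of 930.4 in the IDR list, and the tallest line, at for, 1508.

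Of the 22 gene lists fixed beforehand, 3 differed from lists of protein-coding genes matched on span length, and the genes of cytosolic ribosomal proteins stood farthest apart. Of 92 ribosomal protein genes, 74 (80.4%, exact 95% interval 70.9 to 88.0) had a summit within 5 kb, against 30.4 expected. The strongest were at RpS27 (rank 59), RpS4 (rank 95) and RpL7 (rank 109), 13, 5 and 44 bp from the TSS. Of 73 genes for mitochondrial ribosomal proteins, 37 (50.7%) had a summit against 21.3 expected, led by mRpS23 (rank 17), mRpS10 (rank 28) and mRpL41 (rank 35); the summit at mRpS23 lay nearest to the TSS of its neighbour CenG1A. Odorant and gustatory receptor genes had fewer, 16 of 119 (13.4%) against 43.0 expected; the strongest in their territories, at Gr5a, Or85f and Gr32a, lay nearest to the TSS of the neighbours Tre1, RpL34b and Idua.

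Each of these 3 lists had an adjusted p of 0.00147 after Benjamini-Hochberg adjustment over the 22 lists, from an unadjusted two-sided permutation p of 0.0002, the smallest that 10000 random lists give. When each summit was given only to the gene with the nearest TSS, at any distance, the mitochondrial list no longer passed (11% against 9.25% expected, adjusted permutation p = 0.842). Nor did it with the limit of 5 kb kept, a setting chosen after seeing the data (9.59% against 7.99%, adjusted permutation p = 0.88). Genes side by side can share a summit, and genes, not embryos, are the units of this test. Over the genome, 5546 of 13968 protein-coding genes (39.7%) had a summit within 5 kb.

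Among the segmentation genes, summits were found at some members and not at others, and none of the 3 lists passed the adjusted threshold. Of 9 pair-rule genes, 4 had a summit against 3.87 expected (adjusted permutation p = 1). The strongest were at odd, at slp2 (rank 290, 4327 bp from its TSS) and at the promoter of hry, also called hairy (rank 1552). No IDR summit lay within 5 kb of eve, run, ftz, prd or opa. With each summit given to the nearest TSS at any distance, 5 pair-rule genes had one against 1.80 expected (adjusted permutation p = 0.0743). With the limit of 5 kb kept, 4 did against 1.68 (0.316). Matched on other TSSs nearby, 4 did against 1.82 (0.339). These last settings were chosen after seeing the data. The count was below its expectation in replicate 2 alone (3 against 4.05) and when matched among genes with a name (4 against 4.10). Of 11 genes in the gap list, 3 had a summit against 5.09 expected (adjusted permutation p = 0.635). These were cad (rank 1172, nearest to the TSS of Pomp), hb at its promoter (rank 1922) and btd (rank 4127, nearest to the TSS of nej). The list counts cad with the gap genes, although cad acts upstream of them. Kr, kni, knrl, gt, tll, hkb, oc and ems had none. In single replicates, btd lost its summit in replicate 2 alone, and ems and knrl gained 1 each in replicate 1 alone. Of 11 segment polarity genes, 6 had a summit against 5.90 expected (adjusted permutation p = 1), the strongest at ptc, the receptor of Hedgehog (rank 547), nkd (rank 564) and en (rank 2598), and none at wg, gsb, gsb-n, mid or H15. With each summit given to the nearest TSS at any distance, which changes the assignment and drops the limit of 5 kb together, 9 segment polarity genes had a summit (81.8% against 35.0% expected, adjusted permutation p = 0.0264). With the nearest TSS and the limit kept, a setting chosen after seeing the data, 5 had one (45.5% against 33.9%, adjusted permutation p = 0.851), so the call came with the loss of the limit.

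Lists of signalling and hormone genes lay above their expectation without passing the threshold. All 10 genes of the ecdysone response list had a summit against 6.13 expected (adjusted permutation p = 0.0766), the strongest at the nuclear receptor genes Hr3 (rank 79), Eip75B (rank 221) and Hr4 (rank 261). Among the 10, E2f1 (rank 1604) encodes a cell-cycle factor, and the list was not tested without it. Of 13 genes of the Notch pathway, 10 had a summit against 5.45 expected (adjusted permutation p = 0.0766). The best placed were E(spl)m3-HLH (rank 156) and the neighbours E(spl)m7-HLH and E(spl)m8-HLH, which shared a summit at the promoter of gro (rank 300). The Notch list passed when the IDR list was limited to its 2145 strongest peaks (76.9% against 29.0%, adjusted permutation p = 0.0066) and in replicate 2 alone (84.6% against 42.7%, adjusted permutation p = 0.0187). It did not pass within 1 kb (adjusted permutation p = 0.12), by nearest TSS at any distance (0.0654) or in replicate 1 alone (0.0836). Its E(spl) members all had a summit and lie side by side in 1 stretch of 100 kb with 19 IDR summits. Of the other members, Ser, Su(H) and H had none. Random lists draw genes singly, so these p-values do not allow for neighbours in 1 dense locus. Of 13 genes of dorsoventral patterning and of the Egfr and Dpp pathways, 9 had a summit against 6.84 expected (adjusted permutation p = 0.635), led by brk, aos (rank 252) and spi (rank 406).

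No tissue list passed the adjusted threshold. Of 16 mesoderm and heart genes, 12 had a summit against 8.45 expected (adjusted permutation p = 0.279). Their strongest was in the territory of Mef2, the muscle differentiation factor (rank 31), at the promoter of its neighbour Pdrg1, followed by zfh1 (rank 567) and tin (rank 704). Of 17 neural genes, 3 had a summit against 7.79 expected (unadjusted permutation p = 0.028, adjusted permutation p = 0.103): pros (rank 800, at the promoter of its neighbour mgr, 64 bp from the TSS), D (rank 1145) and Dr (rank 3856). Of 10 gut and renal genes, 5 had a summit against 4.85 expected (adjusted permutation p = 1), led by fkh (rank 232) with bowl and drm after it. Hox genes and their cofactors gave 6 of 11 against 6.62 expected (adjusted permutation p = 1), with Abd-B (rank 453), Antp (rank 711) and hth (rank 1055) the strongest. Leg and disc patterning genes gave 8 of 12 against 7.26 expected (adjusted permutation p = 1), led by Dll (rank 525), bab1 (rank 677) and bab2 (rank 832). Blood genes gave 3 of 7 against 4.02 expected (adjusted permutation p = 0.945), namely ush, srp and kn. The strongest summit at ush (rank 3) lay in its intron, nearest to the TSS of cbt. That at srp (rank 1819) lay nearest to the TSS of GATAe. That at kn (rank 3440) lay at the promoter of its neighbour BEAF-32, 43 bp from the TSS. Replicate 2 alone gave 5 blood genes against 4.08 expected and replicate 1 alone 3 against 4.02, neither past the threshold. Trachea and salivary gland genes gave 4 of 10 against 5.60 expected (adjusted permutation p = 0.75), with trh (rank 338), CrebA (rank 1394) and bnl (rank 1541) the strongest. Axon guidance genes gave 10 of 13 against 8.0 expected (adjusted permutation p = 0.656), led by fra (rank 488, nearest to the TSS of CG33752), NetB (rank 591, nearest to that of hog) and Sema1a (rank 917).

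Of the lists chosen for contrast, these also did not pass the adjusted threshold. Proteasome genes had a summit in 15 of 48 cases against 16.3 expected (adjusted permutation p = 1), and the strongest of these, in the territories of Rpt5, Prosbeta2R2 and Rpn5, lay nearest to the TSS of the neighbours Hrd3, cno and Hpf1. Antimicrobial peptide genes gave 6 of 14 against 3.40 expected (adjusted permutation p = 0.448). The summit shared by CecA1 and CecA2 lay 26 bp from the TSS of RpS7, and that at Def nearest to magu. Within 1 kb, 0 of the 14 had a summit against 1.07 expected, and by nearest TSS at any distance 0 against 1.00. Jonah serine protease genes gave 3 of 16 against 4.51 expected (adjusted permutation p = 0.877), in the territories of Jon25Biii, Jon66Ci and Jon66Cii. The first lay 66 bp from the TSS of betaggt-I, and the other 2 genes shared 1 summit, 177 bp from the TSS of CG7120. Chorion and yolk genes gave 1 of 12 against 3.92 expected (adjusted permutation p = 0.279), in the territory of Yp3, where the strongest summit lay 171 bp from the TSS of rdgB.

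**Figure D4:**
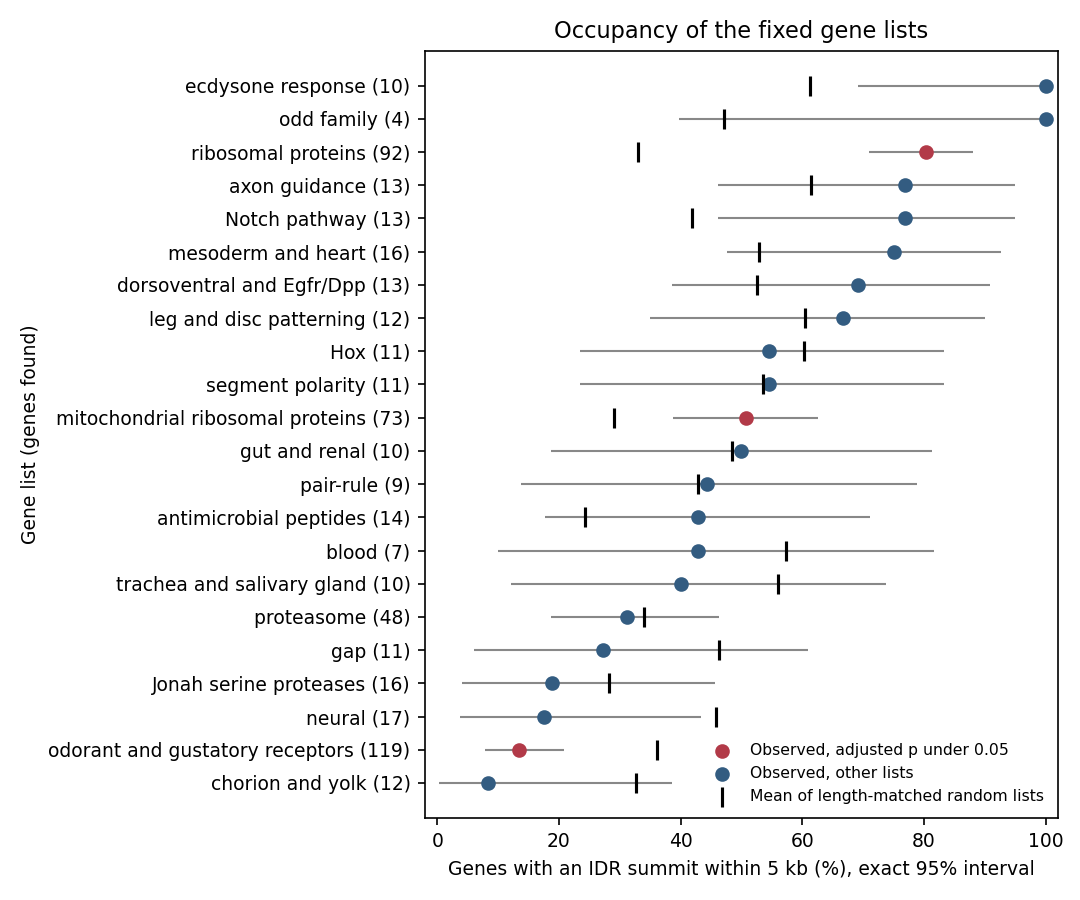
Share of the genes of each of the 22 lists (y axis, number of genes found in the annotation in brackets) with an IDR summit within 5 kb (x axis, percent); points with lines are observed shares with exact 95% intervals, red where the adjusted p was under 0.05, and black ticks are means of length-matched random lists. Ribosomal proteins (80.4% against 33.0% expected), mitochondrial ribosomal proteins (50.7% against 29.1%) and odorant and gustatory receptors (13.4% against 36.1%) are the 3 red points.

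The binding word of Odd was present at few summits. ACAGTAGC, on either strand, lay within 100 bp of 37 of the 4291 summits (0.862%, exact 95% interval 0.608 to 1.19), against 0.361% of windows of the same size 1000 bp to each side, a ratio of 2.39 (adjusted exact p = 0.0347 over 12 words, two-sided sign test). The same bases in reverse order, CGATGACA, gave a ratio of 0.756 (adjusted exact p = 0.736). The call for the word of Odd was lost within 50 bp of the summit (ratio 3.0, adjusted exact p = 0.0502), in the 2145 strongest peaks (2.57, adjusted exact p = 0.181) and in replicate 2 alone (1.94, adjusted exact p = 0.111) and replicate 1 alone (2.21, adjusted exact p = 0.156). It was kept within 250 bp (1.76, adjusted exact p = 0.00949), against shuffled summit sequence (1.80, adjusted exact p = 0.0253) and for the word without its first base (1.38, adjusted exact p = 0.0284). It was also kept with 1 summit per region, a setting chosen after seeing the data (2.57, adjusted exact p = 0.0304). No relation of the word to peak strength was detected: Spearman's rho between signal rank and its presence was -0.008 across peaks (permutation p = 0.604).

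The word of Dref, a promoter-binding factor of growth and replication genes, lay at 1.93% of summits, 3.61 times the flanks (adjusted exact p = 3.19e-09). The GAGA word lay at 6.27%, 1.48 times the flanks (adjusted exact p = 2.93e-07), but its ratio was 1.03 within 50 bp of the summit (adjusted exact p = 0.666). The homeodomain word TAATTA lay at 16.2%, 1.32 times the flanks (adjusted exact p = 1.25e-06), but at 0.970 times the frequency in shuffled summit sequence with the same pairs of neighbouring bases (adjusted exact p = 0.857). The RUNX word was less frequent than in the flanks (ratio 0.685, adjusted exact p = 0.0299), a call lost in 5 of the other settings. The words of Zelda (ratio 0.964), Caudal (0.989), POU factors (0.918), TCF (0.866), M1BP (2.06) and the E-box (1.04) did not pass, with adjusted p of 0.054 for M1BP. M1BP passed within 250 bp (ratio 2.99, adjusted exact p = 4.17e-09), in replicate 2 alone (3.21, adjusted exact p = 0.000793) and against shuffled summit sequence (6.36, adjusted exact p = 1.46e-05). The E-box passed within 250 bp (1.14, adjusted exact p = 0.00456) and against shuffled sequence (2.97, adjusted exact p = 5.96e-30). POU passed in opposite directions, at 0.780 within 250 bp (adjusted exact p = 0.00456) and at 1.23 against shuffled sequence (adjusted exact p = 0.0489). Against shuffled sequence, Caudal (1.26, adjusted exact p = 0.0489) and TCF (0.739, adjusted exact p = 0.0253) also passed.

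A scan of all words of 7 bases found 756 more frequent at summits than in flanks and 1251 less frequent, each at an adjusted p under 0.05. The first 10 by p were made up almost wholly of A and T, led by ATATTTA at 21.7% of summits against 11.6% of flanks. The words outside this AT-rich set among the 30 first shared the bases CAGTG: CAGTGTA (5.71% against 1.70%, ratio 3.36), ACAGTGG (ratio 2.69), CACAGTG (ratio 2.52) and TACAGTG (ratio 2.54). The 2 words of 7 bases inside the word of Odd, ACAGTAG and CAGTAGC, ranked 482 and 751, with ratios of 1.81 and 1.38 (adjusted exact p = 0.0107 and 0.0488). Flanks differ from summits in base composition, which this scan does not correct.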

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

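Signal in data outside the comparisons above was found in the dm3 version of the pooled relaxed list. It held 25 peaks on heterochromatic contigs outside the chromosome arms: 10 on 3LHet, 7 on XHet, 5 on 2RHet, 2 on 3RHet and 1 on 2LHet. In the dm3 IDR list, 1 peak lay on such a contig, 3LHet. The relaxed lists of replicates 1 and 2 held 39 and 15 such peaks. No control sample was analysed here, so these counts were not tested against any expectation, and no explanation was tested. The groups held too few samples for a test of outlying samples, and there was no second group to compare.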

How the results depend on the processing

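Of 539 values under alternatives, 485 kept their side of the threshold or moved by less than their interval. A change of direction between 2 values that both missed the threshold was counted among these. Of the 485, 187 were checks of whether a named gene kept or lacked its summit in a single replicate. The cause of each change below was not tested unless stated. The 2145 strongest peaks are fewer by construction. Summits of replicates matched in 79.2% of the 1000 strongest and 49.2% of the 20000 strongest peaks, in 76.1% within 500 bp, and in 64.8% by 50% reciprocal overlap. The Spearman correlation of the replicates' signal was 0.769 in the 2145 strongest peaks. With promoters of 1000 bp, the 5' untranslated share was 0.163% (adjusted p = 0.00466, n = 4291) and the intron share 31.7%. The intron share was 36.3% in the 2145 strongest peaks, 39.1% against 49.3% of the lowest-ranked peaks (5.6e-21), and 36.0% to 39.6% in single replicates. Single replicates gave 921 to 956 summits on 3L, past the threshold in replicate 1 alone, and 669 to 709 on X. With no placements on Y, chosen after seeing the data, 755 were expected on X and its 694 summits passed (adjusted p = 0.032, n = 4291). With the nearest TSS at any distance, which also drops the limit of 5 kb, shares past the threshold were 100% for the odd family, 81.8% for segment polarity, 69.2% for dorsoventral, Egfr and Dpp genes (0.0499) and 90% for ecdysone genes, and mitochondrial ribosomal proteins fell to 11% (0.842). With the limit kept, chosen after seeing the data, segment polarity did not pass (45.5%, 0.851), mitochondrial ribosomal proteins did not either (9.59%, 0.88), and the odd family (100%, 0.0396), dorsoventral (69.2%, 0.0458) and ecdysone genes (90%, 0.0396) did. The ecdysone list, which includes E2f1, passed within 1 kb (100%, 0.0165). Notch genes passed in the 2145 strongest peaks (76.9%), when matched on other TSSs nearby, a setting chosen after seeing the data (76.9%, 0.0264), and in replicate 2 alone (84.6%, 0.0187) but not replicate 1 alone (76.9%, 0.0836). The E(spl) members of the Notch list lie close together, as do drm, sob and odd, which random lists of singly drawn genes do not copy. The ratio of the word of Odd was 3.0 within 50 bp, 2.57 in the strongest peaks and 1.94 to 2.21 in single replicates, with the call lost in each, and 1.38 to 2.57 in the 4 settings that kept it. Against shuffled sequence the direction turned for the homeodomain word (0.970) and for POU (1.23). Words of 7 bases numbered 492 more and 659 less frequent within 50 bp, and 491 and 673 in the strongest peaks. The dm3 density was not run, for lack of dm3 lengths. No paired analysis was possible because there was 1 group. Unknown depth limits the comparison of list lengths and signal between replicates.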

Other observations

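The tests of clustered tRNA genes, of dense stretches elsewhere and of 1-base variants of the word of Odd, and the choice of the genes and stretches named in this part, came after the results were seen; the other tests were written down before they were run.

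Among protein-coding genes, ush, which encodes a cofactor of GATA factors, had the most summits within its territory (18), followed by CG1677 (17), sbb (15), RapGAP1 (14) and shn (13). These are long genes, and their counts were not corrected for length. Among stretches of 100 kb, the one with the most IDR summits lay on 2L from 3560001 to 3660000 and held 24; sob, odd and for lie in it. The next held 23 (2L, 430001 to 530000, with ex, ush and cbt) and 20 (2L, 2130001 to 2230000, with aop). A stretch with 19 held the E(spl) genes and gro (3R, 25990001 to 26090000), and one with 18 held noc (2L, 14430001 to 14530000). The median over all stretches was 2.00.

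The strongest of the 37 summits with the word of Odd lay nearest to Aldh-III (rank 115), followed by aru (rank 293). Others lay at the promoters of E(spl)m3-HLH (rank 1281) and fng (rank 2290), and 2 lay in introns 12197 and 14691 bp from the nearest TSS of pnt (ranks 1450 and 3274). No gene group was tested among these summits. None lay among the 24 summits of the region of drm, sob and odd.

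Ribosomal protein genes carried summits in 74 of 92 cases. Close spacing of promoters does not account for this, since lists matched also on the number of other TSSs in the territory gave 32.0 expected (adjusted permutation p = 0.0022). Recovery of DNA at any heavily transcribed gene stays open: 5.17% of 290 tRNA genes had a summit within 500 bp, against 3.01% of positions placed singly (p = 0.044, n = 290), as that explanation predicts, but p was 0.144 when the tRNA genes of an arm were rotated together to keep their clusters. Binding through the word of Odd was not detectable, with the word at 0 of 70 ribosomal protein promoter summits (0%) where 0.481 were expected from other promoters, too few to decide, and a wider translation group was not shown either, with summits at 34.6% of translation factor genes against 40% expected (permutation p = 0.512) and 50% of aminoacyl-tRNA synthetase genes against 40.6% (permutation p = 0.569). No biological explanation can be set against these, as the design has 1 group and no control sample was analysed here.

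The word of Odd was at 0.862% of summits. A tight IDR threshold does not account for this low share, since the share among the 25709 relaxed summits below it was lower, 0.533% (Fisher's exact test, two-sided p = 0.0121). Summits with the word were still left out: 137 lay below the threshold, against 37 above it, and their share was above the 0.405% of the left flanks (exact sign test p = 0.0391). Imprecise summits may still contribute: the word occurred 24.9 times per Mb at 101 to 250 bp from the summit (95% interval 17.0 to 35.1) and 44.1 times within 100 bp (31.2 to 60.5), and these intervals overlap; the flanks had 18.1 (14.3 to 22.6), which overlaps the first of the 2. Dilution by promoters cannot be told apart from chance, with the word at 1.03% of distal and 0.663% of promoter summits (Fisher's exact test p = 0.246; 37 summits in all). A 1-base variant in its place also stays open. Of 24 variants none passed the adjustment. Among the 3 with an unadjusted p under 0.05, the highest ratio was 2.00 for ACAGAAGC (adjusted exact p = 0.159). The ratio was 1.96 for ACAGTGGC, which holds the bases CAGTG of the scan and lay at 1.21% of summits. Without its last base, as ACAGTGG, it lay at 7.64% in the scan (ratio 2.69, adjusted exact p = 1.55e-22). The word of Odd without its last base, ACAGTAG, lay at 2.17% (ratio 1.81, adjusted exact p = 0.0107). The scan does not correct for base composition, so it cannot decide between them.

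Summits were dense around odd itself. Within 20 kb of odd the pooled relaxed list held 37 peaks, more than around 98.3% of protein-coding genes, and the replicates gave 98.8% and 98.6%. This was planned as a test of extra copies of the locus in the transgenic flies, but it restates the pattern, would be as high with bound sites alone, and lends extra copies no support. Dense stretches occur elsewhere too, at loci with no transgene named in the labels: 6 stretches of 100 kb elsewhere held more pooled relaxed peaks than the 86 in the densest stretch that spans odd, among them those of noc (104) and emc (98), with a median of 21 over all stretches. By IDR summits, none held more than the 24 of the stretch with odd. Such density therefore also arose without a named transgene. Extra copies stay open, as the size of the inserted fragment is not given in the sources used here and no control sample was analysed here. Binding of Odd at its own locus, as a hypothesis, was not separated from them.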
